A study of Mus musculus with 12 samples.

How the data were processed

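RNA was measured in 12 whole tibialis anterior muscle samples of mice, all taken 5 days after an injection of glycerol, which injures the muscle and is followed by fat formation within it. Per the labels, 6 samples were wild type controls and 6 came from mice in which Pparg was conditionally deleted in fibro-adipogenic progenitors (FAPs), the resident mesenchymal cells of muscle that can become adipocytes. The labels do not say whether the libraries of a group come from separate animals, so p-values measure only the spread between these samples. Per the labels' protocols, messenger RNA was selected with poly-T beads and sequenced on an Illumina platform. The protocol describes both a directional and a non-directional library and does not say which was made.

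The gene table deposited by the authors holds whole-number read counts per gene, with no normalization. Reads were processed with fastp, HISAT2 2.0.5 and featureCounts on the mouse genome GRCm38 (mm10), per the submitters' processing notes. The strand setting of the counting is not given in the sources used here, so reads of genes that overlap on opposite strands may not have been told apart. A second table deposited by the authors holds FPKM values, proportional within each library to the count divided by the gene length of the table. The denominator of the FPKM was between 1.00 and 1.02 times the library size after TMM scaling, and how the authors chose it is not given in the sources used here. The gene table lists 54532 gene identifiers with coordinates. Of these, 54495 occur in the GENCODE M21 annotation of GRCm38 and 53585 have the same coordinates there.

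Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings (a minimum count of 10 and a minimum total of 15), which left 16393 genes. Libraries were scaled by TMM. Knockout and control were compared with robust quasi-likelihood F tests, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are knockout minus control on the log2 scale, and standard errors were derived from the fold change and its F statistic. CPM values use the TMM library sizes, and log2 CPM values a prior count of 2. The step was tested on simulated counts with the means and library sizes of the 12 libraries. The changed genes were drawn from those with higher mean counts, and each library was simulated independently. Genes of low count and libraries that deviate together are therefore not covered. Of 100 genes changed 1.5-fold, 65 were recovered, of 100 genes changed 2-fold, 86 were recovered, and 5 of 156 calls were false.

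The design, the alternatives, the rule for named genes and 41 gene lists were fixed before the data were examined. Of the 640 genes on the lists, 634 were found and 597 were tested. The list of sex-linked genes served as a check of the libraries, and the other 40 lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 lists. Camera was repeated with an estimated correlation, and fry was run beside it. A score per library, the mean log2 CPM of the tested members of a list, was compared between groups by a two-sided exact permutation test over all assignments of the libraries to groups of 6. Correlations between scores were computed within each group of 6 with exact permutation p-values. Named genes are Pparg, up to 12 protein-coding genes with the largest rise and 12 with the largest fall among those past the threshold with a mean log2 CPM of at least 1, and up to 4 members of each list with the smallest p. Members that complete a count of genes past the threshold, such as Rbp4 and Fasn, were named after their values were seen, and other genes outside this rule are named as such where they appear. One gene that the rule selects is not reported here; it stays in the fit and in the counts of genes.

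Shared sequence between genes was measured as the share of 50-base words of the longest GENCODE M21 transcript that occur in another gene. None of the genes that the rule names for the size of their change shared 50% or more of these words with another gene; Gm9625, a pseudogene outside the rule, shared 50.8% with Rplp0. No library was counted as a duplicate: over the 30 pairs of libraries within groups, counts differed by more than sampling noise, with chi-square values per degree of freedom from 13.1 to 161. The alternatives covered the scaling, the test (DESeq2 1.42.0 and limma-voom with quality weights), the low count filter, the replicate number as a block, a surrogate variable (sva 3.50.0), the FPKM values with a pseudocount of 1, and each library left out in turn. Others were added after the data were seen: the mitochondrial share of counts as a covariate, the libraries with the lowest such share left out, and the libraries grouped into sets by the state of loci with discrete high and low levels.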

Results

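Gene expression was measured by RNA sequencing of whole tibialis anterior muscle, a fast muscle of the lower hind leg, 5 days after glycerol injury. The 6 control libraries were compared with 6 libraries from mice with Pparg deleted in FAPs. The title of the series concerns fat within muscle and functional recovery. The comparison asks which genes differ in injured muscle when FAPs lack Pparg, the nuclear receptor that drives adipocyte differentiation. Library totals ranged from 15716056 to 29790720 counts. They averaged 21460700 ± 3041150 counts in controls and 20907300 ± 5208930 in knockouts (SD, n = 6 each, exact permutation p = 0.820). The 13 protein genes of the mitochondrial genome took between 2.66% and 10.8% of the counts, 6.65% ± 2.89 in controls and 5.74% ± 2.52 in knockouts (SD, n = 6 each, exact permutation p = 0.574). The first principal component, with 24.8% of the variance, did not separate the groups (exact permutation p = 0.801). The second, with 18.7%, differed between them (exact permutation p = 0.00866), though not in every library. Knockout replicates 1 and 2 (-9.22 and -11.3) lay within the control range (-19.4 to -3.82). Knockout replicates 3 to 6 (18.5 to 39.8) lay above it.

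Pparg (ENSMUSG00000000440, chromosome 6, 115360951 to 115490399, plus strand, GRCm38) was lower in the knockout libraries. It stood at 57.4 ± 8.27 CPM in controls and 26.4 ± 10.3 CPM in knockouts (SD, n = 6 each), which is 45.9% of the control level. All 6 knockout libraries, from 15.6 to 43.1 CPM, lay below the lowest control at 45.0 CPM. By this measure no library contradicted its label, but knockout replicate 2, at 43.1 CPM, lay close to that control. The log2 fold change was -1.12 (SE 0.21), with an adjusted p of 0.0299 (edgeR quasi-likelihood, Benjamini-Hochberg). The samples were whole muscle and the count covers the whole gene, so the value does not give the extent of deletion within FAPs. The adjusted p rose to between 0.0515 and 0.0856 when control replicate 1, 2, 4, 5 or 6 or knockout replicate 3, 4 or 6 was left out.

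**Figure D1:**
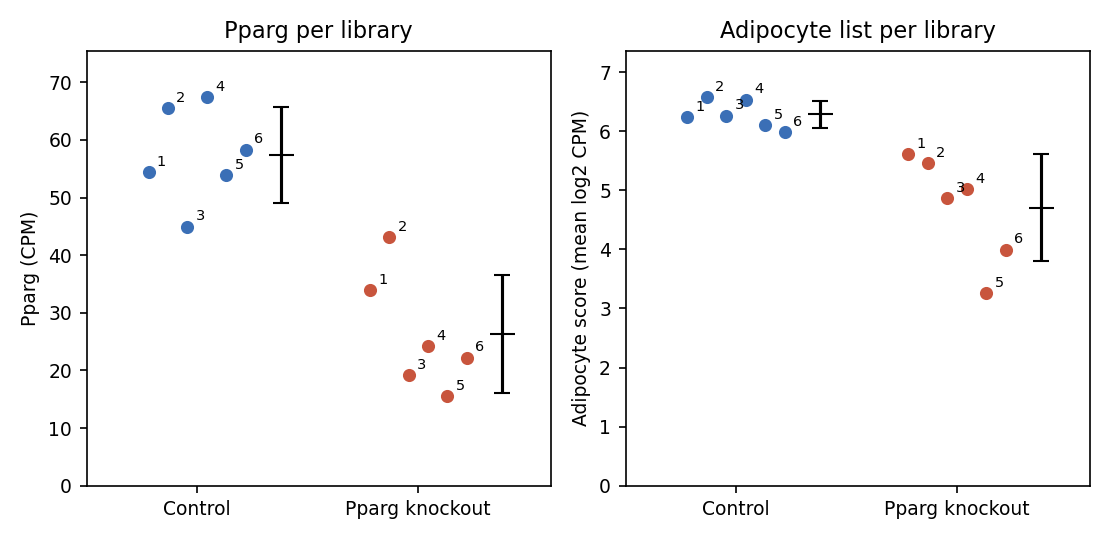
Pparg in CPM (left) and the adipocyte score, the mean log2 CPM of 29 adipocyte genes (right), for each library, with replicate numbers beside the points and the group mean ± SD as a bar (n = 6). The highest knockout library, at 43.1 CPM and a score of 5.62, lies below the lowest control, at 45.0 CPM and a score of 5.98; the highest values of the 2 measures come from different knockout libraries.

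Most of the genes that changed were lower in the knockout, and 8 of the lower genes are on the list of adipocyte markers. Adrb3, the beta-adrenergic receptor of adipocytes, fell from 13.3 ± 4.43 to 2.62 ± 1.68 CPM (log2 fold change -2.35, SE 0.44). Fabp4, the fatty acid binding protein of adipocytes, fell from 2238 ± 453 to 724 ± 307 CPM (log2 fold change -1.63, SE 0.26). Lgals12, a galectin of lipid droplets, Klb, the co-receptor of endocrine fibroblast growth factors, Ffar2, a receptor for short-chain fatty acids, and Tusc5, which takes part in glucose uptake of fat cells, fell by 1.82, 1.67, 1.66 and 1.62 on the log2 scale. Fam110c, Wfdc21, Nnat, Fam83a, Rasd1 and Negr1 completed the 12 largest falls, with log2 fold changes from -1.88 to -1.58. Each of these 12 genes lay below all 6 controls in 6 of 6 knockout libraries, with adjusted p from 0.0151 to 0.0481 (edgeR quasi-likelihood, Benjamini-Hochberg). With each of the 12 libraries left out in turn, all of them lost their call at least 2 times: Tusc5 kept it in 10 fits, Fabp4 in 9, Nnat in 8, Rasd1 in 7, Fam110c, Fam83a and Klb in 6, Adrb3 and Ffar2 in 5, Wfdc21 in 4, Lgals12 in 3 and Negr1 in 2. Nnat lies within Blcap, and Adrb3 overlaps Gm45470, both on the opposite strand, so their counts are uncertain if strand was not used.

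The genes that rose did so by less than 2-fold. Sik1, a kinase of the salt-inducible family, rose from 34.1 ± 3.15 to 54.3 ± 5.41 CPM (log2 fold change 0.67, SE 0.08, adjusted p = 0.00655, edgeR quasi-likelihood). Nuak2, a related kinase, rose from 10.5 ± 0.63 to 17.2 ± 2.88 CPM (log2 fold change 0.71, SE 0.11). Adamtsl2, Zfp979, Tcf7, Hip1r and Jdp2 rose by log2 fold changes of 0.88, 0.87, 0.62, 0.51 and 0.43. The rise was seen above all controls in 6 of 6 knockout libraries for Adamtsl2, Nuak2, Sik1, Hip1r and Jdp2, and in 5 of 6 for Zfp979 and Tcf7. Zfp979 shares 24.6% of its sequence words with Zfp978, and Hip1r overlaps Vps37b and Jdp2 overlaps Gm47863, both on the opposite strand, so their counts are less certain. Sik1 passed without each of the 12 libraries in turn, with adjusted p up to 0.0302 (edgeR quasi-likelihood), whereas Nuak2 kept its call in 11 of these 12 fits, Adamtsl2, Hip1r and Jdp2 in 3, Zfp979 in 2 and Tcf7 in 1.

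In total, 131 of 16393 tested genes passed an adjusted p of 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), 8 higher and 123 lower, and 49 of the lower genes fell by more than 2-fold. Of the 131 genes, 125 were protein coding, and 117 had groups that did not overlap. Over all tested genes 1.43% had groups that did not overlap, against 0.216% by chance. At an unadjusted p under 0.05 there were 1552 genes, 621 higher and 931 lower. The number of called genes depended on single libraries: it was 65, 24, 72 and 15 without control replicates 1, 2, 3 and 4, 204 and 216 without knockout replicates 1 and 2, and 6, 9, 81 and 35 without knockout replicates 3, 4, 5 and 6. At 27 loci with high and low levels, 5 pairs of libraries agreed in 81.5% to 100% of states. With counts summed over such sets of libraries, 4 sets of controls (control replicates 1 and 6 each alone) and 3 of knockouts, edgeR called 0 genes, with 1017 at an unadjusted p under 0.05.

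**Figure D2:**
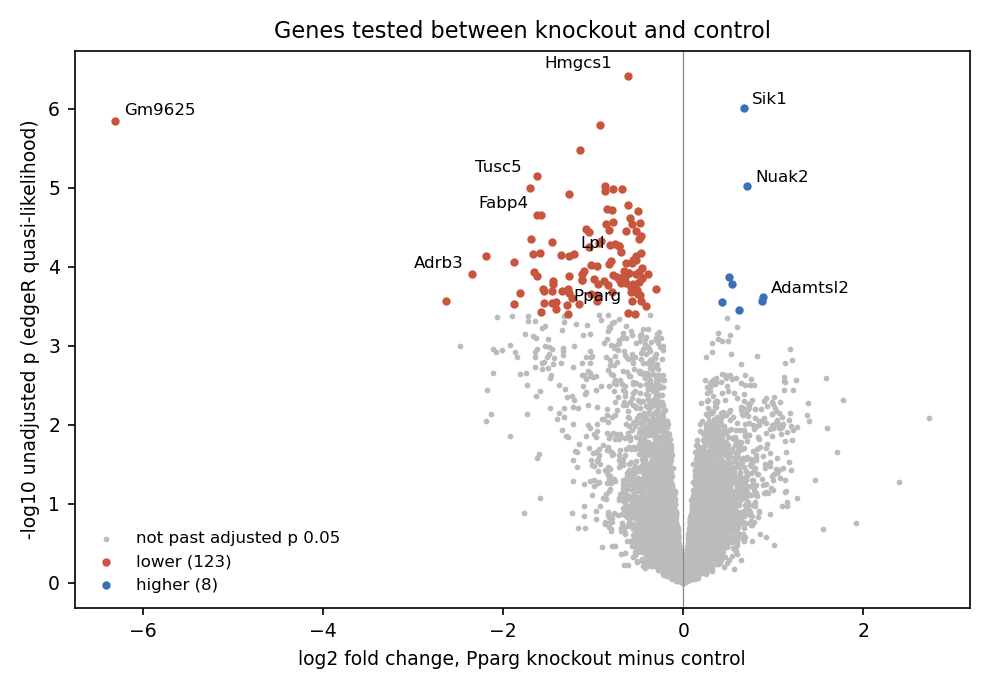
Each point is 1 of 16393 tested genes, with the log2 fold change of knockout minus control on the x axis and -log10 of the unadjusted p (edgeR quasi-likelihood) on the y axis. Of the genes past an adjusted p of 0.05, 123 lie to the left of 0 and 8 to the right; the point at -6.31 is Gm9625, a pseudogene at 46.5 ± 23.2 CPM in controls and 0.57 ± 0.14 CPM in knockouts, which shares 50.8% of its sequence words with Rplp0.

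Markers of mature adipocytes were lower as a group. Of 29 tested adipocyte genes, 8 fell, 0 rose and 21 did not pass over all genes. When adjusted over the list alone 26 fell, and 29 of 29 had negative log2 fold changes with a median of -1.45. Those that fell were Tusc5, Fabp4, Nnat, Lgals12, Adrb3, Aqp7, Rbp4 and Lpl, the lipoprotein lipase, which went from 1307 ± 112 to 563 ± 218 CPM (SD, n = 6 each, log2 fold change -1.22, adjusted p = 0.0249, edgeR quasi-likelihood). Adipoq, the adipocyte hormone adiponectin, stood at 336 ± 87.6 CPM in controls and 100.1 ± 64.0 CPM in knockouts with an adjusted p of 0.123 (edgeR quasi-likelihood), and was chosen after its values were seen. Camera gave the list an adjusted p of 6.92e-33, against an adjusted p of 0.190 with an estimated correlation, and fry an adjusted p of 0.0193. The adipocyte score was 6.28 ± 0.23 in controls and 4.70 ± 0.91 in knockouts, a difference of -1.58 or 2.99-fold, with the 2 groups fully apart (SD, n = 6 each, exact permutation p = 0.00216, the smallest that all assignments of 6 libraries to each group can give).

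Known targets of Pparg and the enzymes of fat synthesis were lower as well. Of 20 tested Pparg targets, 4 fell over all genes (Fabp4, Lpl, Acsl1 and the glycerol channel Aqp7) and 14 when adjusted over the list alone, with a median log2 fold change of -0.86. Camera gave an adjusted p of 2.1e-13, against an adjusted p of 0.190 with an estimated correlation and an adjusted p of 0.0193 with fry. Of 20 genes of lipogenesis, 5 fell over all genes and 12 when adjusted over the list alone, with a median of -0.56. Dgat1, which makes triglycerides, fell from 71.9 ± 7.95 to 40.0 ± 8.80 CPM (log2 fold change -0.85), and Srebf1, a transcription factor of lipid synthesis, from 141 ± 22.2 to 79.8 ± 15.6 CPM (log2 fold change -0.83). Acsl1, Agpat2 and Fasn, the fatty acid synthase, fell by 1.10, 1.27 and 1.16 on the log2 scale, and Agpat2 overlaps Egfl7, and Srebf1 overlaps Rai1, on the opposite strand. With each library left out in turn, Dgat1 kept its call in 9 of 12 fits, Srebf1 in 8, Lpl in 7, Acsl1 in 6, Agpat2 and Fasn in 4 and Aqp7 in 3; Rbp4, of the adipocyte list, kept it in 6. For lipogenesis camera gave an adjusted p of 2.1e-13, against an adjusted p of 0.107 with an estimated correlation and an adjusted p of 0.00892 with fry. The scores of the adipocyte, Pparg target and lipogenesis lists were the only 3 of 40 that passed an exact permutation test after adjustment (adjusted p = 0.0289 for each). These lists share members and are not separate results: Fabp4, Lpl and Aqp7 are on the adipocyte and Pparg target lists, and Acsl1 is on the Pparg target and lipogenesis lists.

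FAP, preadipocyte and lipid-associated macrophage lists were lower with camera. Of 20 FAP genes 2 fell, 7 when adjusted over the list alone: Col15a1, a basement membrane collagen, went from 293 ± 23.2 to 204 ± 23.4 CPM (log2 fold change -0.52), and Gsn, the actin-severing protein gelsolin, from 845 ± 96.7 to 575 ± 75.1 CPM (log2 fold change -0.56). Col15a1 kept its call in 8 of the 12 fits with 1 library left out and Gsn in 4, and Col15a1 overlaps Gm12426 on the opposite strand. The FAP list had a median of -0.17 and a camera adjusted p of 6.28e-06, against an adjusted p of 0.355 with an estimated correlation, and its score lay below all controls in knockout replicates 3, 5 and 6 only. Of 15 preadipocyte genes, Fabp4 and Pparg fell, 5 genes did when adjusted over the list alone, and Cebpa had a log2 fold change of -0.71 with an adjusted p of 0.0794 (edgeR quasi-likelihood). Pparg is the deleted gene itself and Fabp4 is also on the adipocyte list, so their falls are not separate evidence on preadipocytes. Camera gave an adjusted p of 0.0029, and an adjusted p of 0.472 with an estimated correlation, and the score lay below all controls in knockout replicates 3, 4, 5 and 6. Of 18 lipid-associated macrophage genes, Fabp4 and Lpl fell, both of which adipocytes also express, and 3 fell when adjusted over the list alone. Camera gave an adjusted p of 1.91e-05, and an adjusted p of 0.472 with an estimated correlation, and the score lay below all controls in every knockout replicate but 2. Extracellular matrix genes had 0 of 28 members past the threshold, over all genes or over the list alone, and a median of -0.13; Col6a2 stood at 903 ± 57.7 CPM in controls and 627 ± 162 CPM in knockouts. The camera adjusted p of 0.0415 for that list became an adjusted p of 0.899 with an estimated correlation, and it was lost, at 0.0633 to 0.308, without control replicate 2 or 6 or knockout replicate 2, 3, 4 or 5. Fatty acid oxidation had 0 of 20 members past the threshold and 2 adjusted over the list alone, with a median of -0.16, a camera adjusted p of 0.00389 and an adjusted p of 0.819 with an estimated correlation; without knockout replicate 6 the camera adjusted p was 0.143.

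Lists of muscle regeneration were higher with camera, although no member passed the test over all genes. All 23 genes of differentiating myocytes had positive log2 fold changes, with a median of 0.25 and 0 past the threshold adjusted over the list alone. Their score lay above the control range (8.11 to 8.56) only in knockout replicates 3, 4 and 5 (8.92, 8.76 and 8.83); replicates 1, 2 and 6 (8.37, 8.29 and 8.21) lay within it. Myog, the transcription factor myogenin, stood at 248 ± 49.5 CPM in controls and 331 ± 62.0 CPM in knockouts (log2 fold change 0.42, adjusted p = 0.296, edgeR quasi-likelihood). Of 18 satellite cell and myoblast genes 16 were positive, with a median of 0.31, and Cdh15, Myod1 and Cd82 rose when adjusted over the list alone. The 18 genes of the neuromuscular junction and of denervation were all positive, with a median of 0.29, and Dok7, which is needed to form the junction, stood at 28.5 ± 3.61 against 42.9 ± 9.14 CPM and rose only when adjusted over the list alone (1 gene). The junction score was 5.98, 5.80 and 5.72 in knockout replicates 3, 4 and 5, but 5.34, 5.33 and 5.36 in replicates 1, 2 and 6, close to the controls (5.23 to 5.36). The satellite cell score was likewise highest in knockout replicates 3, 4 and 5 (6.09, 5.94 and 5.74, controls 5.04 to 5.60). Camera adjusted p-values were 4.36e-06, 6.14e-06 and 3.69e-07 for these 3 lists, against adjusted p = 0.472, 0.472 and 0.355 with an estimated correlation. Slow fibre genes (12 of 12 positive, median 0.30) and the regenerating myosin list (6 of 6 positive, median 0.28) had camera adjusted p-values of 0.00244 and 0.00618, and an adjusted p of 0.472 with an estimated correlation for both. The regenerating myosin list also holds Tnnt2 and Chrng, which are not myosins. The lists of muscle regeneration share members, such as Tnnt2 with differentiating myocytes, and Myog and Ncam1 between differentiating myocytes and the junction. The slow fibre score lay above the control range (5.24 to 5.82) only in knockout replicates 2, 3 and 5 (6.57, 6.16 and 5.89), and the regenerating myosin score above its control range (9.36 to 9.89) only in knockout replicates 3 and 5 (10.23 and 10.27).

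The list of T and NK cells, whose genes stood at low levels, was higher with camera too. Of 18 tested genes 17 had positive log2 fold changes, with a median of 0.55, and 0 passed over all genes. Their score lay above the control range (-0.06 to 1.22) only in knockout replicates 2 and 4 (1.81 and 1.41); replicates 1, 3, 5 and 6 (0.81 to 1.06) lay within it (exact permutation p = 0.0476 over all 12 libraries, adjusted p = 0.212). Gzma, Il2rb, Ncr1 and Klrb1c rose when adjusted over the list alone (4 genes). Gzma, a granzyme, stood at 3.13 ± 1.88 CPM in controls and 7.47 ± 2.09 CPM in knockouts, and Il2rb, an interleukin 2 receptor chain, at 2.99 ± 1.49 and 6.91 ± 2.36 CPM (SD, n = 6 each, adjusted p = 0.132 and 0.0979, edgeR quasi-likelihood). Camera gave the list an adjusted p of 3.9e-07, against an adjusted p of 0.468 with an estimated correlation. Wnt, TGF-beta and BMP signalling genes (21 of 23 positive, median 0.17) and interferon genes (13 of 20 positive, median 0.16) had camera adjusted p-values of 0.00389 and 0.0185, against adjusted p = 0.355 and 0.899 with an estimated correlation, and 0 members of either passed over all genes or over the list alone. All 6 knockout interferon scores (4.98 to 5.69) lay within the control range (4.30 to 6.01). The interferon call was lost, at 0.0548 to 0.487, without control replicate 1, 2, 5 or 6 or knockout replicate 1 or 2.

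**Figure D3:**
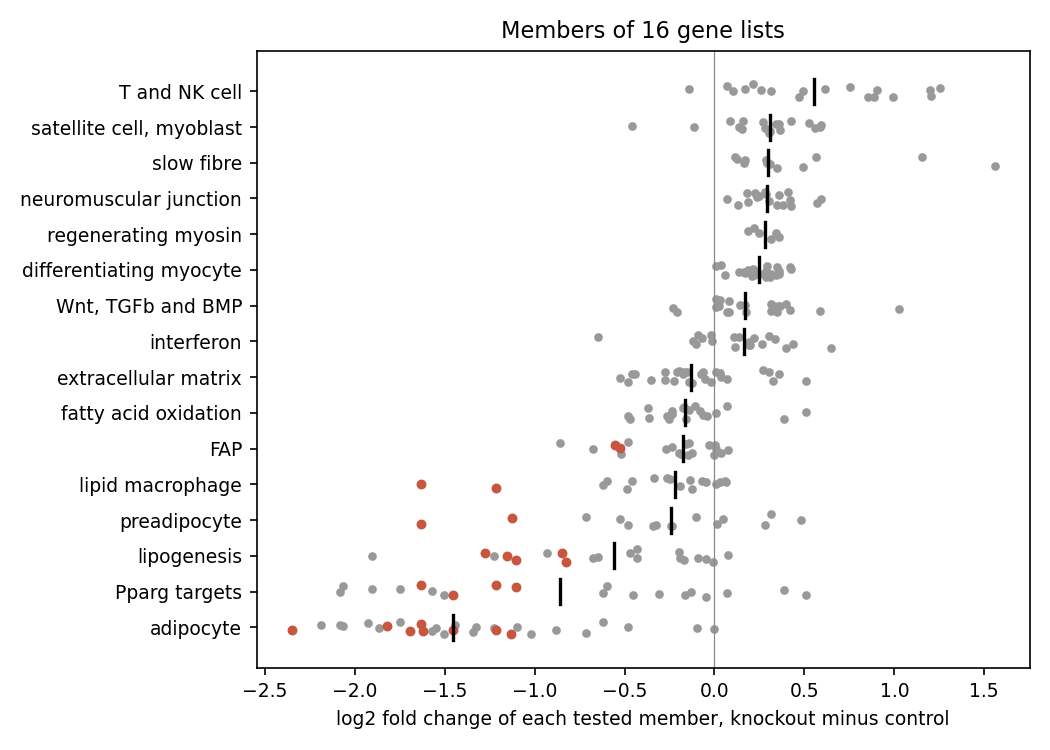
Log2 fold change of knockout minus control (x axis) for each tested member of the 16 gene lists called by camera at its preset correlation, with list medians as black bars and members past an adjusted p of 0.05 over all genes in red. The adipocyte list, at the bottom, has its median at -1.45, and the list of T and NK cells, at the top, at 0.55; 0 of the 16 lists passed with an estimated correlation.

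The other 24 lists did not pass with camera. Each is given with its median log2 fold change and its camera adjusted p. They covered mature fast fibres (median 0.12, adjusted p = 0.226), pan-macrophage genes (-0.05, 0.275), pro-inflammatory macrophages (-0.01, 0.816) and repair macrophages (-0.05, 0.661). Further cell types were neutrophils (-0.14, 0.272), B and plasma cells (0.16, 0.941) and dendritic and mast cells (-0.03, 0.316). They also included endothelium (-0.08, 0.174), mural cells (0.02, 0.896), Schwann cells (-0.05, 0.941) and tenocytes (-0.54, 0.739). Pathway lists were beige and brown fat (-0.07, 0.739), atrophy (-0.01, 0.968), the cell cycle (0.06, 0.305), hedgehog signalling (0.05, 0.755) and factors secreted by FAPs in regeneration (0.12, 0.316). The rest were complement (-0.10, 0.152), oxidative phosphorylation (-0.04, 0.384), glycolysis (0.09, 0.490), stress and unfolded protein genes (-0.07, 0.195), immediate early genes (0.11, 0.0843), mitochondrially encoded genes (-0.29, 0.305), erythroid genes (0.22, 0.455) and skin keratin genes (0.10, 0.305). In 4 lists the signs of the median, the mean or the test differed, among them B and plasma cells, with a positive median and a downward test. Gpd1, on the lists of mature fast fibres and glycolysis, is also an adipocyte gene and stood at 449 ± 103 CPM in controls and 210 ± 94.4 CPM in knockouts (adjusted p = 0.125, edgeR quasi-likelihood).

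Whether other tissue programmes followed the amount of adipocyte RNA was examined within each group of 6 libraries. The adipocyte score was set against the scores of differentiating myocytes, mature fast fibres, pan-macrophage genes and extracellular matrix, which makes 8 relations. None passed: Pearson's r ranged from -0.29 to 0.60 and Spearman's rho from -0.37 to 0.60, with exact permutation p from 0.200 to 0.992 for r and from 0.242 to 1 for rho. After adjustment p was 0.992 for every Pearson's r and at least 0.878 for every rho. Without the 2 libraries farthest from the median adipocyte score, r ranged from -0.96 to 0.99 and 4 of the 8 turned sign.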

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

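In this part the tests of what could set the knockout libraries apart from each other were chosen only after the result was seen. A library was picked out where its distance to the nearest library of its group was large against the range of the group, by Dixon's test at the 95% level. Of 420 groups of 6 tested, 24 gave such a library; chance gives about 1 in 20. Knockout replicate 2 had the highest erythroid score, 7.68 against 5.60 in the next library, with Hba-a1 at 700.0 CPM, Hbb-bt at 131 CPM, Hba-a2 at 122 CPM and Alas2 at 38.4 CPM, and also the highest Ddit4, at 56.3 CPM. Control replicate 1 had the lowest erythroid score of its group, 2.38, and the highest coordinate on the second principal component, -3.82. Knockout replicate 6 had the lowest scores of its group for mature fast fibres (8.79 against 10.02 in the next library), glycolysis (8.07) and fatty acid oxidation (5.63), and the highest Rrm2, at 65.3 CPM. Control replicate 6 had the lowest scores of its group for Pparg targets (7.05), satellite cells and myoblasts (5.04) and skin keratins (0.43), the lowest Cox4i1 (576 CPM) and Egr1 (34.3 CPM), and the highest Zfp979 (10.5 CPM). Control replicate 5 had the highest score for lipid-associated macrophages (8.55), the highest Lyve1 (37.2 CPM) and the highest mt-Nd4l (90.9 CPM). Control replicate 2 had the highest S100a8 (6.17 CPM), knockout replicate 1 the highest Rgs5 (134 CPM). Knockout replicate 3 had the lowest Emcn (10.9 CPM).

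The adipocyte scores of the knockout libraries spanned 3.26 to 5.62 against 5.98 to 6.57 in controls. A mislabelled control among the knockout libraries is argued against by the score, since the highest knockout score lay -2.85 control SDs from the control mean. That SD rests on 6 libraries. Pparg in knockout replicates 1 and 2 (33.9 and 43.1 CPM) also lay below all controls. In replicate 2, however, it was close to the lowest control (45.0 CPM, control mean 57.4 ± 8.27 CPM), so Pparg argues little for that library. On the second principal component, however, both lay within the control range (-9.22 and -11.3 against -19.4 to -3.82). The share of mature muscle would give a negative correlation between the adipocyte and mature fast fibre scores. Over the 6 knockout libraries Pearson's r was 0.42 (exact permutation p = 0.397), of the opposite sign. These are too few libraries to decide, so this explanation stays open. Incomplete loss of Pparg, the biological explanation that the design offers, may contribute: Pparg and the adipocyte score had an r of 0.83 (exact permutation p = 0.0472, adjusted over both groups 0.0944) and a rho of 0.89 (exact permutation p = 0.0333, adjusted 0.0667). Without the 2 libraries farthest from the median of Pparg r was 0.67, and in controls it was 0.54 (exact permutation p = 0.286). The explanations cannot be told apart here, because adipocytes themselves express Pparg and the adjusted p misses the threshold. The adipocyte scores also followed the library sets described below. The set means were 5.54 for knockout replicates 1 and 2, 4.95 for 3 and 4, and 3.63 for 5 and 6. The exact p counts libraries of a set as independent, which they may not be. A shared animal or litter, raised below, therefore stays open for this spread too.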

How the results depend on the processing

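The settings with the mitochondrial share, the library sets, and the surrogate variable for lists were chosen only after the data were seen. The 8 higher and 123 lower genes became 67 and 332 with DESeq2 (4 genes without an adjusted p), 62 and 331 with limma-voom and quality weights, 28 and 209 with 1 surrogate variable, 13 and 163 with limma on log2 FPKM, and 25 and 158 with the mitochondrial share as a covariate. The replicate block gave 15 and 221. The deviations of same-numbered libraries correlated between -0.13 and 0.46, over 0.1 in 2 of 6 pairs, and 2 of 6 libraries correlated best with their own number. The shared numbers therefore show no pairing throughout. These correlations were not tested and cannot exclude a factor shared by some pairs. Other scalings and filters gave totals of 92 to 138. With 1 library left out the counts ranged from 1 to 25 higher and from 5 to 191 lower. Without the 3 libraries with the lowest mitochondrial share (control replicates 2 and 6 and knockout replicate 6) they were 4 and 5, with fewer samples. With counts summed over library sets they were 0 and 0 in edgeR (1017 at an unadjusted p under 0.05). This used 7 sets in place of 12 libraries. A random effect for the sets, fitted with limma-voom without quality weights, gave 6 and 117. That fit was not run without the sets, so the effect of the sets on its calls is not known. The adipocyte score kept its direction and its side of the threshold throughout, from -2.16 (median of members) to -1.29 (without knockout replicate 5), and over the sets the difference was -1.54 (exact permutation p = 0.0286, the smallest that the sets allow).

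Pparg stayed lower in every alternative, with adjusted p from 7.6e-05 with DESeq2 to 0.265 with summed sets. Its log2 fold change was -1.12 with no low count filter (adjusted p = 0.0979, edgeR, with 31961 genes tested), -1.01 without the 3 libraries of lowest mitochondrial share (0.227), -1.12 with summed sets (0.265), and between -1.32 and -1.002 with 1 library left out. Camera called 8 lists higher and 8 lower; with an estimated correlation it called 0 and 0, with 4 lists at an unadjusted p under 0.05, and fry called 0 higher and 3 lower. The adipocyte list had an adjusted p of 0.190 with an estimated correlation. The block added 1 list, mature fast fibres, and changed no other call of camera. With 1 library left out, 3 of the 16 called lists lost their call at least once and 10 of the 24 others gained one. Without the 2 libraries farthest from the median adipocyte score, r turned to 0.81 for mature fast fibres and -0.56 for extracellular matrix in controls, and to -0.36 and 0.99 in knockouts, none of which was tested with 4 libraries. Scaled by library size, r ranged from -0.53 to 0.62 and rho from -0.66 in knockouts to 0.83 in controls, both for differentiating myocytes, and none passed (unadjusted p at least 0.0583, adjusted p at least 0.467). In controls r became -0.47 for mature fast fibres, and turned from -0.07 to 0.28 for pan-macrophage genes. For the called genes that the rule names, other than Pparg, 445 of 700 results over all settings stayed past the threshold, 255 did not and 0 reversed; direction was counted as reversed only where a value was called. For called genes named outside the rule (Rbp4, Fasn, Hmgcs1, Insig1, Acat2, Mgl2, Gm9625 and Adipor2) 142 of 200 stayed past it, 58 did not and 0 reversed. The cause of the other differences was not tested. The Y-linked covariate was not run, since 0 counts of those genes were found in all 12 libraries. Xist, which is expressed in female tissue, had from 8575 to 23684 counts per library, so all 12 libraries read as female.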

Other observations

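In this part the tests by 100 splits of the libraries were set before their results were seen, and those of the splits that keep library sets whole, of the sterol list, of the library sets and of the share of adipocyte RNA were chosen only after the result was seen; the test of chromosomal position was part of the design, but how its outcome would be read was set only after the result was seen. Genes outside the rule for named genes are given here because of their values. Hmgcs1, an enzyme of cholesterol synthesis, had the smallest p of all genes and fell from 86.2 ± 6.48 to 56.2 ± 4.47 CPM (SD, n = 6 each, log2 fold change -0.62, SE 0.07, adjusted p = 0.00637, edgeR quasi-likelihood), below all controls in 6 of 6 knockout libraries. Insig1, which senses sterols, and Acat2, which takes part in sterol synthesis and shares 45.9% of its sequence words with Acat3, fell by 0.78 and 0.52 on the log2 scale. With each library left out in turn Hmgcs1 kept its call in 12 of 12 fits, Insig1 in 10 and Acat2 in 4 (adjusted p up to 0.0918, edgeR quasi-likelihood). A hypothesis is that sterol synthesis may be lower as a whole in the knockout. Of 19 tested members of a sterol list written for this purpose, without these 3 called genes, 18 had negative log2 fold changes with a median of -0.16, and 0 passed over all genes or over the list alone. Camera with an estimated correlation gave an unadjusted p of 0.0605, and 0.0405 with Acat2 kept in. At its preset correlation camera gave an unadjusted p of 2.18e-05, fry one of 0.0184, and the score an exact permutation p of 0.0519. These tests fall on both sides of 0.05, so the hypothesis stays open. Mgl2, a lectin of macrophages and dendritic cells, fell from 54.6 to 28.7 CPM (log2 fold change -0.92, adjusted p = 0.00655, edgeR quasi-likelihood), while the list of dendritic and mast cells did not pass.

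For the genes, chance can be excluded if the 12 libraries are independent: of 100 splits of the 12 libraries into groups of 6, drawn from 462, 1 gave as many genes as the real split, which was the real split itself with 131, and the highest of the others gave 4. The sets of libraries described next may not be independent (their deviations agreed more, by 0.261), and most splits break them up. The splits that keep the 4 control and 3 knockout sets whole number 10, too few for a share under 0.05; the real one gave 131 genes and the highest of the others 6. At an unadjusted p under 0.05 the real one gave 1552 genes and the highest of the others 1899. For the number of lists chance cannot be excluded: 40 of the 100 splits gave 16 lists or more, and the highest of the others gave 25. Camera at its preset correlation called the adipocyte list in 63 of the 99 other splits, so its camera call alone does not set the groups apart.

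Pairs of libraries agreed in the state of most of 27 loci with discrete high and low levels, among them Gapdh (23.9 to 963 CPM): control replicates 4 and 5 had the same state at 100% of them, knockout replicates 3 and 4 at 96.3%, 1 and 2 at 85.2%, 5 and 6 at 85.2%, and control replicates 2 and 3 at 81.5%. Reads shared with processed pseudogenes are consistent with the make-up of the loci, of which 48.1% were pseudogenes against 4.85% of other tested genes (odds ratio 18.2, Fisher's exact p = 9.43e-11). Libraries of a set that share an animal or litter are consistent with their deviations over the other 16366 genes, whose correlation was higher by 0.261 within sets than between other libraries of a group (permutation p = 0.0168). The mean r was 0.02 within sets and -0.24 otherwise, where centring on groups of 6 alone gives -0.2. It ranged from -0.01 to 0.22 in 4 pairs but was -0.22 for control replicates 2 and 3, so that pair gives no support. A difference in background between the groups stays open: agreement was 5.39 percentage points higher within groups than between, and 37 of 462 splits gave as much, the highest of the others 11.7. Gm9625, a pseudogene on chromosome 13, was the only called gene among the loci, at 46.2 to 63.3 CPM in 5 controls, 1.27 CPM in control replicate 1 and at most 0.83 CPM in the knockouts, which may reflect such a background. It shares 50.8% of its sequence words with Rplp0, so its counts are uncertain.

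Lists of T and NK cells, of the neuromuscular junction and of regenerating muscle were higher with camera while adipocyte genes were lower. A lower share of adipocyte RNA would raise all other genes. The 144 fallen and adipocyte genes took 1.79% of counts in controls and 0.91% in knockouts. Losing these reads alone would lift the other genes by 0.01 on the log2 scale. RNA that adipocytes make from genes outside the 144 was not counted, so the full rise may be larger. The shares use library totals, whereas the list scores are TMM scaled. The 0.01 is below the score difference less 2 SE for T and NK cells (0.0930) and for the neuromuscular junction (0.0591). That does not argue against a lower share of adipocyte RNA, because the full rise is not known. The SE also counts libraries of a set as independent, which they may not be. The difference was not tested over the sets. The junction score rose in knockout replicates 3, 4 and 5 and stayed close to the controls in replicates 1, 2 and 6. The T and NK cell score exceeded the control range only in knockout replicates 2 and 4. For differentiating myocytes and satellite cells the rise of 0.01 from the counted genes was small against score differences of 0.230 and 0.265. Less 2 SE these were -0.0552 and -0.0527, so the spread between libraries was too wide to tell whether the scores differ. A different share of mature muscle cannot be told apart either. The myocyte score difference adjusted for the mitochondrial share was 0.245 (SE 0.15). With 40 of 100 splits giving as many lists, whether these lists differ between the groups at all stays open.

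Strain sequence linked to the floxed allele or to the driver could gather calls near Pparg or near Pdgfra, a usual driver in FAPs that the labels do not name. Within 20 Mb of either gene 3 of 427 tested genes were called (Pparg, Adipor2 and Klb), against 128 of 15966 elsewhere, an odds ratio of 0.875 (two-sided Fisher's exact p = 1), and windows of 5 and 50 Mb gave 1.97 (p = 0.276) and 1.15 (p = 0.615). Pparg, the targeted gene, is counted as a call in each window, although its own fall is what the deletion aims at. No such gathering was found, and calls this few cannot exclude one.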
